A study of Homo sapiens with 22 samples.

How the data were processed

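The series comprised 22 libraries in 6 groups, all from human cell lines. HFFc6 is a subclone of telomerase-immortalised human foreskin fibroblasts, and H1 is a human embryonic stem cell line. ATAC-seq, in which the transposase Tn5 cuts open chromatin, was run on 8 HFFc6 and 2 H1 libraries. The 8 HFFc6 ATAC libraries carry 2 R labels and 4 T labels, whose meaning is not stated, so some may be repeats of the same material. Cut&Tag, in which an antibody tethers Tn5 to a chromatin protein, was run on 2 HFFc6 libraries for CTCF and 2 for the cohesin subunit SMC1. The titles of these Cut&Tag libraries begin with HFF1 while their cell line label is HFFc6, and the cell line label was used. Cut&Run was run on 4 HFFc6 libraries for H3K4me3 and 4 for H3K27ac. The 10 libraries for SMC1, H3K4me3 and H3K27ac were not analysed here.

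The values came from 4 deposited peak lists. Each of 3 lists is named by every library of its group in the labels (HFFc6 ATAC, H1 ATAC and HFFc6 CTCF), so each was a single call for the group and held no values per library. The remaining list is named for CTCF in human embryonic stem cells and no sample label used here describes it. Its assay and libraries are therefore not given in the sources used here, and it is called the hESC-named CTCF list throughout. Per the submitters' processing notes, BWA, MACS2 and bedtools were used with the genome build hg38. Their versions, the filters, the handling of replicates, any background control, and any Tn5 offset of the read ends are not given in the sources used here. In each deposited list the authors gave every peak a score, which was not used. The deposited fold enrichment is the peak caller's ratio of signal over its background. The deposited −log10 p-value and −log10 q-value columns are also the peak caller's own, and every list stopped at a q of 0.05. These peak values are the authors' and were used to describe, rank or filter peaks within a list. Across lists, fold enrichment was used only in the Spearman rho between CTCF fold enrichment and the highest fold enrichment of the overlapping HFFc6 ATAC regions. That rho rests on ranks. The shares of regions past a q limit are also set side by side between lists, as a description of each list.

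Peaks on chromosomes 1 to 22 and X were kept, and overlapping peaks of one list were merged, which joined 0 peaks. A region counted as found in another list at an overlap of at least 1 bp. Overlap was compared with 1000 circular shifts of the first list along each chromosome, a one-sided permutation test whose smallest p is 0.001. Standard errors (SE) came from a jackknife over the 22 autosomes, and 95% intervals on shares are Wilson intervals. Neither contains variation between libraries. Read depth is unknown from peak lists, and the lists differed in length, in region width and, where stated, in number of libraries. No test between cell lines was possible, and differences are differences between lists. Whether the libraries of a group came from separate cultures is not stated.

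Genes came from a RefSeq table of assembly GRCh38 patch 14, the same build as the lists, with 19970 protein-coding and 18177 lncRNA genes on the chromosomes used. It gave gene starts and ends without strand or exons. The planned transcription start site was therefore replaced by either end of a gene, and exons were not told apart from introns. Location was scored as within 1 kb of an end of a protein-coding or lncRNA gene, elsewhere in such a gene, or between genes, and was set against the mean of 100 circular shifts. The planned search for the CTCF motif was not run because no genome sequence was used here.

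Each ATAC region was assigned to the protein-coding gene with the nearest end. For 15 gene lists fixed before the data were examined, the median of HFFc6-only minus H1-only regions was ranked among 10000 random lists of equal size, matched on deciles of total regions. The percentile describes these lists of peaks and is no p-value. The text names members of the gene lists, the 10 genes with the largest and the 10 with the lowest difference, and the 5 CTCF regions of highest fold enrichment among shared regions and among HFFc6-only regions in HFFc6-only ATAC regions. That rule was also fixed before the data were examined. TDGF1 was matched under its current symbol, CRIPTO. Single values of some list members are not reported here.

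The steps were tested on simulated data. With 155746 HFFc6 ATAC regions against a copy with 0, 20 or 50% of regions planted, the excess over shifts was 0.00378, 18.7 and 47.5%. The overlap rules gave 0 disagreements with a direct comparison. The gene list check used differences permuted over all 19970 genes, which removed their link to total regions. There, 39 of 40 random lists raised by 3 regions per gene passed percentile 97.5. Of 40 unchanged lists, 5 lay outside the central 95%, more than the 2 or so that the nominal rate gives, so percentiles close to the limits are weak evidence. Because of the permutation, neither rate need hold for the real lists, and the matching on deciles was not tested. For orders of 3 classes over 50000 simulated regions, 0 of 20 random orders exceeded every shuffled order.

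Alternatives were a −log10 q of at least 10, an overlap of 50% of the shorter region, lists of equal number, shifts of 100 kb to 1 Mb, peaks as deposited, gene end windows of 500 bp and 2 kb, all regions within 50 kb of a gene end, and ranking by −log10 q. A width of 500 bp around the summit and the mean in place of the median were added after seeing the data, as were all alternatives for the share of hESC-named CTCF regions in HFFc6 ATAC. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.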

Results

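Open chromatin was mapped in HFFc6 fibroblasts and H1 embryonic stem cells, and CTCF, the zinc-finger protein that anchors chromatin loops, was mapped in HFFc6. The HFFc6 ATAC list held 155746 regions with a median width of 707 bp, covering 124.2 Mb. The H1 ATAC list held 189982 narrower regions, with a median of 301 bp and 70.0 Mb covered. The HFFc6 CTCF list held 82297 regions (median 696 bp) and the hESC-named CTCF list 104785 (median 496 bp). Peak calls were firmer in the HFFc6 ATAC list, where 85.2% of regions had a −log10 q of at least 10, against 48.4% in the H1 list. The corresponding shares were 69.7% for HFFc6 CTCF and 60.5% for hESC-named CTCF. Each list was a single call with no replicates, the HFFc6 ATAC list from 8 libraries and the H1 list from 2.

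The first comparison asked which open regions the fibroblast and stem cell lines share. Of the HFFc6 ATAC regions, 34.7% ± 0.79 (jackknife SE) overlapped an H1 ATAC region, 54067 regions in all. Of the H1 regions, 31.8% ± 1.07 overlapped an HFFc6 region. Shared regions lay at gene ends far more often than line-specific ones. Within 1 kb of a gene end lay 30.2% ± 1.32 of HFFc6 regions shared with H1, against 7.13% ± 0.27 of HFFc6-only regions. The H1 list gave 31.4% ± 1.27 for shared and 7.0% ± 0.41 for H1-only regions. Shifted positions gave 6.78% and 5.86% for the HFFc6 sets and 5.76% and 5.08% for the H1 sets. Inside genes away from the ends lay 59.4% ± 0.44 of HFFc6-only and 53.8% ± 0.79 of H1-only regions, against 50.55% and 50.99% after shifting. Between genes lay 33.5% ± 0.46 of HFFc6-only and 39.2% ± 1.00 of H1-only regions, against 43.6% and 43.9%. Both overlaps exceeded every circular shift and were 4.82 and 5.18 times the mean of the shifts (one-sided permutation test, p = 0.001, the smallest the shifts can give).

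Genes of the pluripotency network carried more H1-only than HFFc6-only regions. Of 24 listed genes, 20 had more H1-only regions, 3 had more HFFc6-only regions and 1 had equal numbers. Among all 19970 protein-coding genes, 7223 had more H1-only regions, 7786 had more HFFc6-only regions and 4961 had equal numbers. SOX2, a core transcription factor of embryonic stem cells, had 78 H1-only and 5 HFFc6-only regions. PRDM14, a repressor of differentiation genes in stem cells, had 13 against 0. The RNA-binding protein gene LIN28A had 6 against 2. NANOG had 1 of each, and DPPA4, LIN28B and LEFTY2 leaned towards HFFc6. A region within 1 kb of either gene end was found in both lists for 10 of the 24 genes, in H1 alone for 10, in HFFc6 alone for 1 and in neither for 3. POU5F1, which encodes OCT4, was among the genes with no such region in either list, although 5 H1-only regions were assigned to it. The list median of −4 was at percentile 0 of the random lists. Its mean, −7.88, was at percentile 4.87, within the central range.

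Genes of the fibroblast matrix and surface leaned the other way. Of 26 genes, 19 had more HFFc6-only regions, 4 had more H1-only regions and 3 had equal numbers. The collagen gene COL5A1 had 34 HFFc6-only against 13 H1-only regions, fibronectin (FN1) 35 against 15, and fibrillin (FBN1) 34 against 15. COL1A2 had 31 against 14. The exceptions were DCN with 26 against 30, THY1 with 6 against 10, FAP with 6 against 9 and CCN1 with 0 against 3. The median of 4 was at percentile 99.8. Most of these genes were open at an end in both lines: 23 of 26 had a region there in both lists, and only COL6A3 and POSTN had one in HFFc6 alone.

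Mesenchymal transcription factors had a median of 3.5 at percentile 97.4, just inside the central range, with 12 of 20 genes leaning to HFFc6 and 5 to H1. RUNX1 had 50 HFFc6-only against 30 H1-only regions, and TWIST2 and RUNX2 each had 32 against 13. ZEB2 had 83 against 106 and OSR1 had 23 against 43. All 20 had a region at an end in both lists. AP-1 and serum response genes, which share JUN, FOSL1 and FOSL2 with the previous list, had a median of 2 at percentile 97.3. Among them 7 of 12 leaned to HFFc6, led by MYC with 78 against 52. Both percentiles lay within the central range and depended on the setting. The mesenchymal percentile was 87.6 with regions within 50 kb of a gene end, 83.0 with stricter peaks, 97.7 at equal numbers and 98.6 with the mean. For AP-1 genes it was 50.7 within 50 kb, 71.6 with stricter peaks, 85.0 at 50% overlap and 98.1 with the mean.

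Genes of other lineages were mixed. Neural progenitor genes had a median of −6.5 at percentile 2.09, and 8 of 10 leaned to H1. OTX2 had 33 H1-only and 0 HFFc6-only regions. Endoderm and mesoderm genes had a median of −5.5 at percentile 4.25, with 7 of 10 leaning to H1 and 3 to HFFc6. FOXA2 had 34 H1-only against 2 HFFc6-only regions, and GATA6 had 6 against 10. The percentile of this list was 0.51 within 50 kb of a gene end and 1.82 at equal numbers, both past the limit. With stricter peaks its median was 0.5 at percentile 4.29. With the mean the neural and endoderm percentiles were 8.45 and 24.9. The melanocyte list had a median of −5 at percentile 2.04, although 3 of its 7 genes leaned to HFFc6 and 4 to H1. TYRP1 had 61 H1-only against 5 HFFc6-only regions, and MITF had 12 against 28. With peaks of −log10 q of at least 10 the neural and melanocyte medians were both 1, at percentiles 6.55 and 24.8. The melanocyte percentile was 5.60 within 50 kb, 10.02 at equal numbers and 26.0 with the mean, all inside the central range. The percentiles of the keratinocyte, endothelial and blood lists were 12.1, 53.6 and 16.0. The keratinocyte percentile was 0.48 within 50 kb and 79.9 with stricter peaks. The percentile was 47.3 for housekeeping genes, 62.6 for CTCF and cohesin genes and 50 for clustered protocadherins. The housekeeping and protocadherin medians were both 0, as was the middle value of their random lists, and 34 of 53 protocadherins had equal numbers. Tied medians were placed midway, so both percentiles say little about a lean.

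Presence of a region at a gene end was counted without a test. Of 16 epithelial junction genes, 9 had an ATAC region at an end in both lists and 7 in H1 alone, with none in HFFc6 alone. E-cadherin (CDH1), CLDN6, CLDN7, OVOL1 and GRHL2 were among the 7. The median difference of −0.5 was at percentile 17.5. All 15 housekeeping genes had a region at an end in both lists. Over all 19970 protein-coding genes the counts were 14081 in both, 1108 in HFFc6 alone, 1655 in H1 alone and 3126 in neither.

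**Figure D1:**
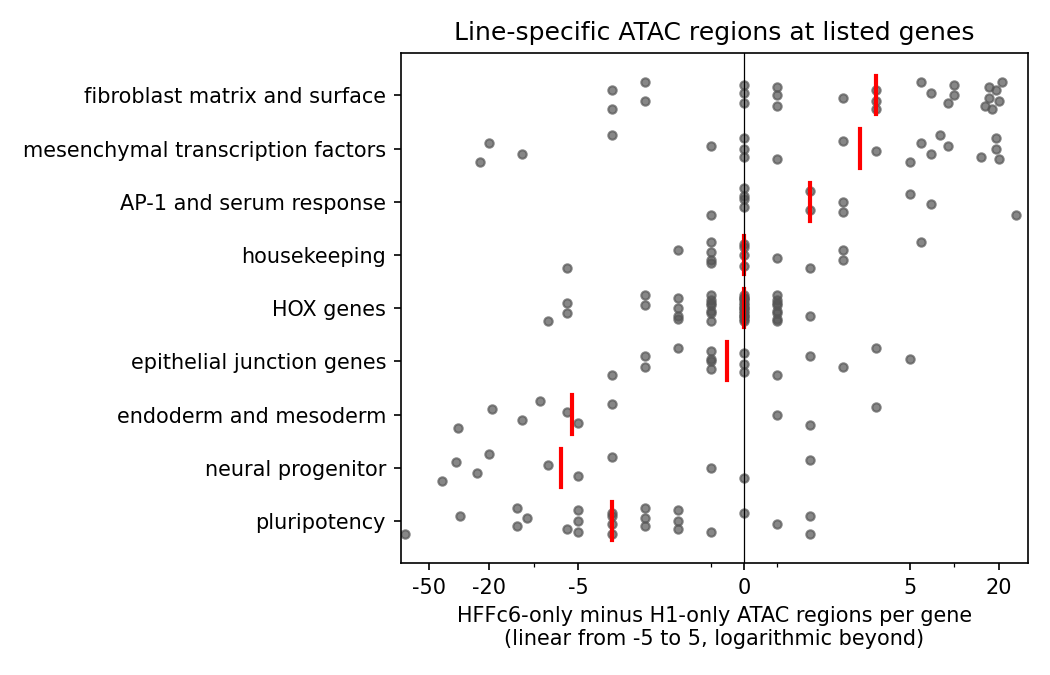
Each point is a listed gene, placed by its HFFc6-only minus H1-only ATAC regions (x axis, linear from -5 to 5 and logarithmic beyond), and red bars mark the list medians. The pluripotency median is -4 and the fibroblast matrix median is 4; points are spread vertically only for visibility.

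HOX genes, which pattern the body axis, had a median of 0 at percentile 49.8, with 9 of 39 leaning to HFFc6, 16 to H1 and 14 equal. This value was unstable. With stricter peaks the percentile was 99.5, with all regions within 50 kb of a gene end it was 0, and with the mean it was 0.41. HOXC4 had 9 H1-only regions against 1, and HOXB1 and HOXB9 each had 7 against 1.

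The 10 genes with the largest excess of HFFc6-only regions were NCKAP5, BLID, LIMCH1, ID2, SPOCK1, DIPK2B, USP25, SLC4A3, HEMK2 and METTL15. NCKAP5 on chromosome 2 (132671788 to 133674836) had 106 against 36, and ID2, an inhibitor of basic helix-loop-helix factors, had 83 against 36. HEMK2 turned to -2 when all regions within 50 kb of a gene end were counted. The 10 with the largest excess of H1-only regions were PTPRD, CSMD3, BRINP3, LRP1B, CDH8, CSMD1, SORCS1, CNTNAP2, GPC5 and GALNTL6. PTPRD, a receptor tyrosine phosphatase gene on chromosome 9 (8314246 to 10613002), had 301 H1-only and 4 HFFc6-only regions. CSMD3 had 247 and 0, and CNTNAP2, a neurexin family gene, had 194 and 26. The median gene length was 1348 kb for the H1-only excess and 229.9 kb for the HFFc6-only excess, against 24.2 kb for all protein-coding genes. At −log10 q of at least 10 the difference at PTPRD and CSMD3 was −94 and −81, and with regions within 50 kb of a gene end it was −6 and −14. NCKAP5 and ID2 moved from 70 and 47 to 13 and 5 within 50 kb.

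The second comparison asked whether CTCF sites lie in open chromatin. In HFFc6, 85.0% ± 0.87 of CTCF regions overlapped an ATAC region of the same line and 51.9% ± 0.69 an H1 ATAC region. These shares were 10.3 and 7.37 times the mean of the shifts (one-sided permutation test, p = 0.001 each, the smallest the shifts can give). Of the hESC-named CTCF regions, 72.6% ± 0.34 overlapped H1 ATAC and 42.7% ± 0.76 HFFc6 ATAC. CTCF regions lay within 1 kb of a gene end in 22.8% ± 0.87 of cases in HFFc6 and 19.4% ± 0.88 in the hESC-named list, against 6.48% and 5.89% after shifting. Among ATAC regions, 69.8% ± 1.40 of HFFc6 regions shared with H1 carried HFFc6 CTCF, against 30.1% ± 0.86 of HFFc6-only regions. H1 regions gave 65.2% ± 1.38 and 30.1% ± 1.24 with the hESC-named list. Cut&Tag also cuts with Tn5, so cutting in open chromatin without the antibody can add to every overlap of HFFc6 CTCF with ATAC. Its part in these shares is not known. The hESC-named list has no stated assay, so its shares may not compare like for like.

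The third comparison set the CTCF lists against each other. Of HFFc6 CTCF regions, 50.9% ± 0.81 were found in the hESC-named list, and 41.3% ± 1.07 of that list were found in HFFc6 (10.8 and 11 times the mean of the shifts; one-sided permutation test, p = 0.001 each, the smallest possible). The 41907 shared CTCF regions were open in both lines in 73.4% ± 0.53 of cases. The 40390 HFFc6-only CTCF regions overlapped HFFc6 ATAC in 87.1% ± 1.16 and H1 ATAC in 18.2% ± 0.39. The 61483 regions only in the hESC-named list were open in H1 in 64.7% ± 0.36 and in HFFc6 in 14.4% ± 0.42. In that class 32.1% ± 0.41 were open in neither line, against 11.6% ± 1.07 of HFFc6-only and 6.0% ± 0.20 of shared regions. CTCF fold enrichment followed ATAC fold enrichment more closely in 35175 HFFc6-only regions (Spearman rho 0.617 across regions, which are not independent replicates) than in 34771 shared ones (0.493). Both sets held only CTCF regions that overlapped an HFFc6 ATAC region. No library without antibody was used here, so the part of HFFc6-only CTCF regions that reflects open chromatin alone is not known.

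**Figure D2:**
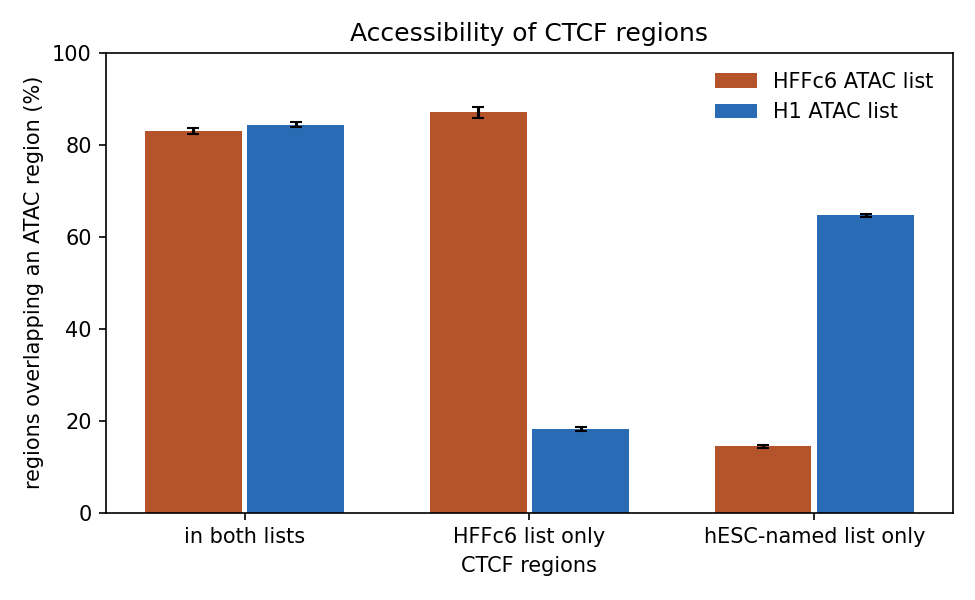
Bars give the percentage of CTCF regions overlapping an ATAC region of HFFc6 (brown) or H1 (blue), for regions in both CTCF lists or in a single list; error bars are jackknife SE over 22 autosomes. HFFc6-only regions reach 87.1% in HFFc6 and 18.2% in H1, and regions only in the hESC-named list reach 14.4% and 64.7%.

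Stronger peaks were shared more often. Over 5 equal groups by fold enrichment, the share of HFFc6 CTCF regions found in the hESC-named list was 23.9% ± 0.61 in the weakest group and 82.5% ± 0.76 in the strongest. The reverse share was 16.3% ± 0.60 and 80.4% ± 0.86. ATAC sharing spanned less, from 21.1% ± 0.39 to 47.6% ± 1.29 for HFFc6 and from 20.1% ± 0.70 to 53.0% ± 1.41 for H1. Median CTCF fold enrichment in the HFFc6 list was 8.20 in shared and 4.69 in HFFc6-only regions.

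**Figure D3:**
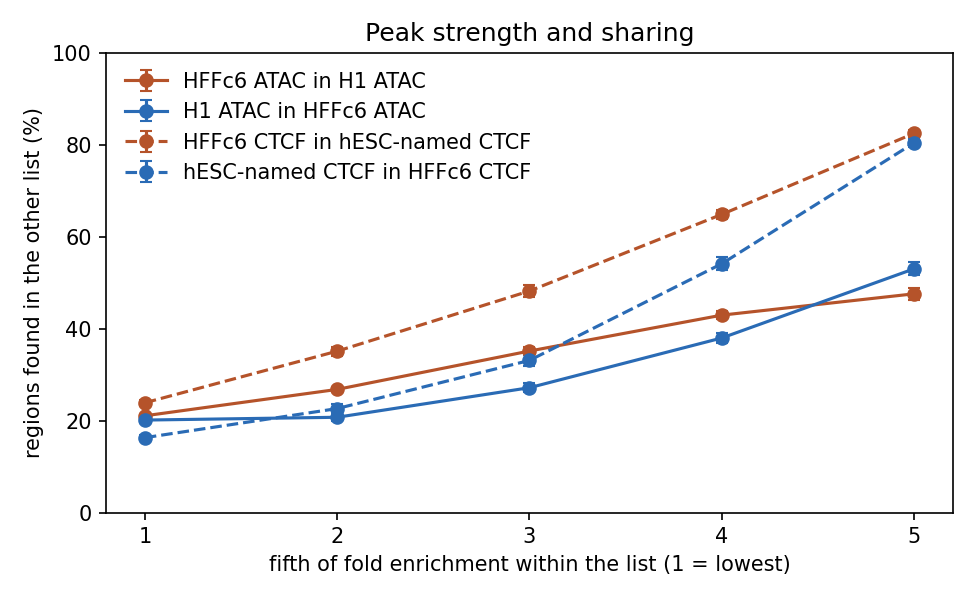
The percentage of regions found in the other list (y axis) is plotted against 5 equal groups by fold enrichment within each list (x axis, 1 lowest); solid lines are ATAC, dashed lines CTCF, and error bars are jackknife SE. CTCF sharing reaches 82.5% and 80.4% in the strongest group, and ATAC sharing 47.6% and 53.0%.

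Of the 26903 HFFc6-only CTCF regions in HFFc6-only ATAC regions, the strongest was on chromosome 17 (53105887 to 53106381, hg38) with a fold enrichment of 32.4. It lay outside KIF2B, the protein-coding gene with the nearest end (716793 bp away), and within 1 kb of an annotated mitochondrial pseudogene, MTCO1P40. The next were outside but nearest to LOC124900995, FAHD2A, GRAPL and TRIM43, with fold enrichments of 32.2 to 20.6. The strongest shared region was on chromosome 17 (43251452 to 43252268), 20591 bp from CCDC200, with a fold enrichment of 37.5 and ATAC regions in both lines. Its HFFc6 ATAC region had the highest fold enrichment of that list, 43.6. Whether repeats or copy number add to the signal there was not tested. The next shared regions were nearest to BSPH1, SULT2A1, TCAF1 and GOLGA6L10, all outside these genes. The SULT2A1 region overlapped an ATAC region in H1 and not in HFFc6.

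The clustered protocadherins, neuronal adhesion genes whose promoters are known CTCF sites, were counted without a test. At the low-coordinate end of the 15 alpha genes, on chromosome 5 from 140786140 to 141012347, the hESC-named list had a CTCF region at 15 and HFFc6 at 6. PCDHA1, PCDHA5, PCDHA6, PCDHA8, PCDHA10, PCDHA11, PCDHA12, PCDHA13 and PCDHAC2 had one only in the hESC-named list. An ATAC region at either end was found in both lists for 7 alpha genes, in HFFc6 alone for 2, in H1 alone for 5 and in neither for 1. Of 16 beta genes, 12 had a CTCF region at the low-coordinate end in both CTCF lists and 3 in the hESC-named list alone. Of 22 gamma genes, 17 had one in both, 3 in HFFc6 alone and 1 in the hESC-named list alone. Over all 53 genes the counts were 35 in both, 3 in HFFc6 alone, 13 in the hESC-named list alone and 2 in neither. Over all protein-coding genes the low-end CTCF counts were 6811 in both, 1440 in HFFc6 alone, 1435 in the hESC-named list alone and 10284 in neither. Strand was not given, so over all genes the low end mixes transcription start sites with the opposite ends. These counts are therefore no like-for-like background. The assay behind the hESC-named list is not given in the sources used here.

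**Figure D4:**
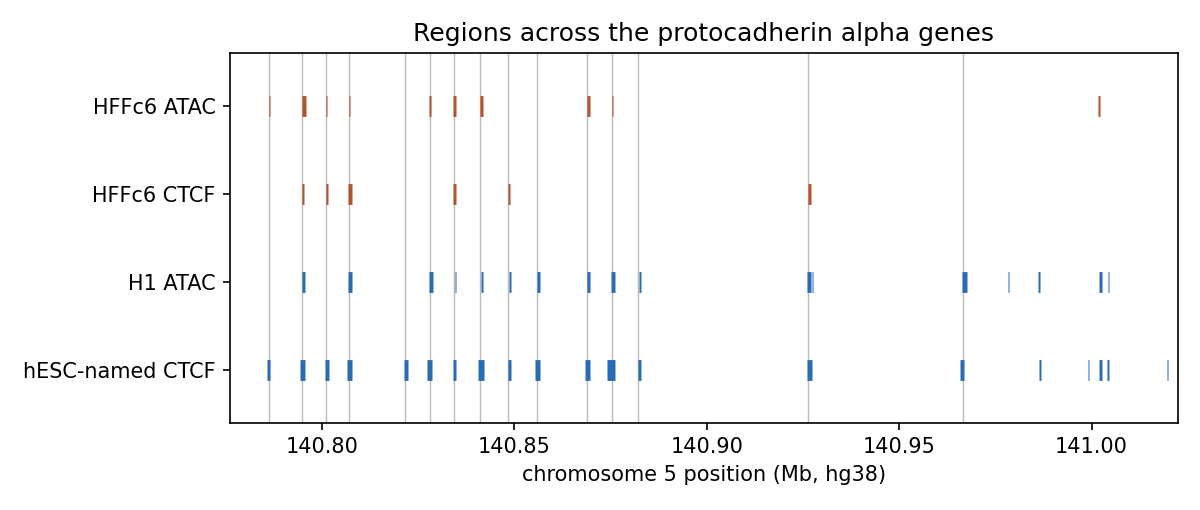
Regions of the 4 lists (rows) are drawn to scale along chromosome 5 (x axis, Mb, hg38), and grey lines mark the low-coordinate ends of the 15 protocadherin alpha genes. The map holds 6 HFFc6 CTCF, 21 hESC-named CTCF, 10 HFFc6 ATAC and 17 H1 ATAC regions.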

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

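Each list also held peaks outside chromosomes 1 to 22 and X, which no comparison used: 534 in HFFc6 ATAC, 275 in H1 ATAC, 207 in HFFc6 CTCF and 259 in the hESC-named CTCF list. They are listed only because the chromosome filter left them out of every comparison, and nothing was tested on them.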

How the results depend on the processing

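A width of 500 bp around the summit, the mean, and all alternatives for hESC-named CTCF in HFFc6 ATAC were chosen after seeing the data. All 8 overlap shares exceeded shifts (permutation p = 0.001) under each of 6 alternatives. HFFc6 ATAC in H1 ranged from 27.9 to 34.7% and HFFc6 CTCF in HFFc6 ATAC from 68.9 to 90.03%. The hESC-named CTCF share in HFFc6 ATAC ranged from 35.1 to 50.6%. Merging joined 0 peaks, so peaks as deposited tested nothing. The cause of the changes below was not tested.

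HFFc6-only CTCF regions were open in HFFc6 in 85.4% (50% overlap), 97.2% (−log10 q of at least 10) and 81.4% (500 bp), and in H1 in 19.5% (q) and 19.1% (500 bp). Regions only in the hESC-named list were open in HFFc6 in 13.2% (50% overlap), 16.7% (q), 15.1% (equal numbers) and 12.5% (500 bp), and in H1 in 59.8% (50% overlap), 70.3% (equal numbers) and 65.6% (500 bp).

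By construction, gene end shares moved with the window. At 500 bp they were 12.7, 11.6, 19.4 and 15.6% for HFFc6 ATAC, H1 ATAC, HFFc6 CTCF and hESC-named CTCF, at 2 kb 19.6, 19.0, 28.2 and 24.7%, and with stricter peaks 16.2, 21.3, 26.8 and 21.4%. Ranked by −log10 q, the gap between the strongest and weakest of 5 groups was 33.0, 44.9, 70.7 and 73.0 points for HFFc6 ATAC, H1 ATAC, HFFc6 CTCF and hESC-named CTCF.

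Gene lists above percentile 97.5 numbered 1, and 2 with stricter peaks, 2 with equal numbers, 2 with 50% overlap and 3 with the mean. Those below 2.5 numbered 3, and 5 within 50 kb, 1 with stricter peaks and 1 with the mean. The 1 with the mean was HOX genes (0.41), so none of the main 3 stayed below 2.5 there. HOX genes (99.5) were also 1 of the 2 above 97.5 with stricter peaks. Of the 20 genes named by size, all kept their direction with stricter peaks, equal numbers and 50% overlap. Within 50 kb 19 did, and HEMK2 turned to -2. Their size was within 1.5 times of the main value for 0 of 20 within 50 kb, 10 with stricter peaks, 19 at equal numbers and 20 at 50% overlap.

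No paired analysis was possible because each list was a single call for its group, and for the same reason no library could be left out. The motif alternatives were not run. Unknown depth limits every comparison: an absent region may lie below detection, and at −log10 q of at least 10 the share of H1 ATAC regions in HFFc6 was 42.7%.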

Other observations

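The tests on chromosome 1 peaks and on chromosome ratios were chosen only after their results were seen, and the runs with the most regions were named after seeing them. Regions of one class lay side by side along chromosomes. The hypothesis that HFFc6-only, H1-only and shared regions follow in random order was tested on 285263 neighbouring pairs. Of these, 47.3% were of one class, above all 1000 random orders within chromosomes, which averaged 37.2% and reached 37.5% at most. Counted by class, 15.9% of pairs were both HFFc6-only, 26.7% both H1-only and 4.67% both shared, against at most 12.9%, 20.9% and 3.79% in random orders. The count by class was added after the pooled value was seen.

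The run with the most HFFc6-only regions, 46 with no H1 or shared region between them, spanned 671.6 kb on chromosome 19 (42634921 to 43306496). It covers the pregnancy-specific glycoprotein genes, PSG1 to PSG9 and PSG11. The next by number of regions held 42 on chromosome 8 (46033147 to 47238573) and 35 on chromosome 14 (105511731 to 106153864). Runs of 28 regions each lay on chromosomes 4 (48992456 to 51825710) and 13 (16239617 to 19598048). Whether repeats or gaps in the assembly lie within these HFFc6-only runs was not checked. H1-only runs held more regions. The one with most held 231 over 2643 kb of chromosome 3 (381452 to 3024098) with the neural adhesion genes CHL1, CNTN6 and CNTN4. Others held 218 regions on chromosome 4 with ADGRL3 and TECRL, 207 on chromosome 13 with KLHL1, and 205 on chromosome 18 with CDH7 and CDH19.

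The same kind of crowding was seen at the 10 genes named for their H1-only excess, which together had 2154 H1-only and 151 HFFc6-only regions. With a −log10 q of at least 10, 10 of 10 genes had more H1-only regions (750 against 134 in total), and 10 of 10 did at equal numbers (1638 against 159). Because the genes were picked for this excess, keeping its sign decides nothing, and weak peaks and the length of the H1 list both stay open. Of the H1-only regions at these genes 34.4% reached that q, against 38.9% of other H1-only regions. A difference between the cell lines also stays open and was not tested.

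HFFc6-only CTCF regions were mostly open in HFFc6 and not in H1, a gap of 68.9 percentage points. Against region width, the gap was 62.3 ± 1.02 (jackknife SE) at 500 bp. With a −log10 q of at least 10 it was 77.7 ± 0.54. That filter kept 85.2% of HFFc6 but 48.4% of H1 ATAC regions, so it cannot decide whether weak H1 peaks were missed. Tn5 cutting in open chromatin without the antibody remains a candidate explanation for part of the HFFc6-only CTCF regions. It predicted a rho between CTCF and ATAC fold enrichment at least 0.1 higher in HFFc6-only than in shared regions. Among regions overlapping an HFFc6 ATAC region the difference was 0.124 ± 0.0098. The sets were not matched on CTCF fold enrichment, whose median over each whole class was 4.69 in HFFc6-only and 8.20 in shared regions. The difference in rho therefore cannot single out Tn5 cutting without the antibody. CTCF binding that differs between the cell lines stays open too, since the motif search that bears on it was not run and the second CTCF list has no stated assay.

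The HFFc6 ATAC peaks of highest q lay on chromosome 1 (631957 to 632965, 633489 to 634418 and 629157 to 630026), each within 1 kb of annotated mitochondrial pseudogenes such as MTCO1P12 and MTND1P23. Mitochondrial reads placed on nuclear copies may explain them. Of the 10 peaks of highest q, 50% (95% Wilson interval 23.7 to 76.3%) lay near such a pseudogene, against 0.0128% of all regions. The interval treats the 10 peaks as independent, although those on chromosome 1 lie close together, as do those on chromosome 21. Each of the other 3 lists had 2 of its 10 peaks of highest q near such a pseudogene. The limit set for calling it the cause was more than 50%, so the test left it undecided for the set. Only genes with symbols of the same pattern as those named were counted, so nuclear copies under other symbols would be missed. The share stood at the limit, so the undecided outcome also rests on this choice. No biological explanation was tested.

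The ratio of H1 to HFFc6 ATAC regions ran from 1.06 on chromosome X to 1.49 on chromosome 18, and its SD over 23 chromosomes on the log2 scale was 0.118, and 0.104 at equal numbers. At a −log10 q of at least 10 the ratio was below 1 on all 23 chromosomes, from 0.631 to 0.946 on gene-rich chromosome 19, with an SD of 0.130. At equal numbers the ratio was high on gene-poor chromosomes 18 (1.20) and 13 (1.10) but also on gene-rich chromosomes 22 (1.12) and 19 (1.10).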
